A study of Mus musculus with 14 samples.

How the data were processed

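Gene expression was measured in mouse embryonic stem (ES) cells of the line R1 and in trophoblast stem (TS) cells of a line that carries a GFP transgene, on Affymetrix arrays of the MG_U74 version 2 set. The set consists of the arrays A, B and C, which hold different probe sets and are called chips here. In all, 14 arrays were analysed, made from 6 RNA preparations, 3 of each cell type, and each chip was analysed alone because its probe sets are its own. Chip A had 2 ES and 3 TS arrays, chip B had 3 and 3, and chip C had 1 ES and 2 TS arrays. TS preparations carry replicate numbers in the labels; ES labels give an unmarked preparation and those marked n+1 and n+2, numbered here in that order, so a shared number does not pair an ES with a TS preparation.

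The deposited values are intensity values on a linear scale, 1 signal per probe set and array, and the submitters' processing notes name MAS5, with no version. The pattern of the values fits a global scaling: the mean after trimming 2 percent at each end lay between 1500.2 and 1500.9 on every array, and differed by less than 5 percent within a chip, so the deposited scaling was kept. No detection calls were used here. The instrument logs deposited with the arrays gave scan days and chip lots, which are coded here as day 1, 2 and so on; the cell type they name was that of the label for all 14 arrays. The processing of the images before MAS5 is not given in the sources used here.

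The 66 control probe sets of each chip were left out. A pseudocount, the 25th percentile of all signals of the chip (221.7 on chip A, 313.3 on chip B and 245.1 on chip C), was added before log2 was taken, so differences are on the log2(signal + pseudocount) scale, which understates changes of dim genes. A probe set was tested if its signal exceeded the array's median on at least as many arrays as the smaller group has (2, 3 and 1 arrays on chips A, B and C), which left 7090 of 12422 probe sets on chip A, 6624 of 12411 on chip B and 8059 of 11868 on chip C. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the variance), and p-values were adjusted by the Benjamini-Hochberg method within a chip, with a threshold of 0.05. On chip C the single ES array was assumed to vary like the TS arrays. The labels do not say that preparations came from separate cultures, so the p-values measure only the spread between these preparations, which may be technical. For arrays, the number of preparations limits the precision.

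Genes were named from the platform annotation: 10833 probe sets on chip A had 1 gene symbol, 396 had several and 1193 none; on chip B these were 10581, 178 and 1652, and on chip C 7717, 150 and 4001. The symbols of 10817, 10550 and 7677 probe sets matched the RefSeq gene table of the assembly GRCm38.p6, which was used for names only, and no symbol changed. Probe sets with several symbols were never named, and no coordinates are given because the array files name no genome build.

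Before the data were examined, 19 lists with 532 entries were fixed: pluripotency and ES cell markers, factors used by both cell types, TS cell and extraembryonic ectoderm markers, differentiated trophoblast, endoderm, germ layer, fibroblast and blood markers, keratins and epithelial junctions, FGF and ERK response genes, the LIF and STAT3 pathway, imprinted genes, DNA methylation and Polycomb, cell cycle, glycolysis and hypoxia response, extracellular proteases and inhibitors, MHC class I and antigen presentation, germ cell genes, and X inactivation and Y-linked genes. Each gene was represented by 1 probe set, from chip A before B before C and then the brightest. Members were counted from the fit of their chip. The shift of a list was tested with limma's camera at a preset correlation of 0.01 on 9204 genes of the 5 preparations on both chips A and B (2 ES, 3 TS), with Benjamini-Hochberg adjustment over the 17 lists with at least 3 genes there. The other 2 lists, germ cell genes and X inactivation and Y-linked genes, had too few. Camera with an estimated correlation and limma's fry were run beside it.

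The genes named by rank were the 8 highest and 8 lowest log2 differences on chip A. On chip B they were 6 and 6, and on chip C 3 and 3. They were taken among probe sets past the threshold with no overlap between the groups and 1 gene symbol. Probe sets ending in _f_at, _s_at, _r_at or _i_at, which can mark cross-hybridisation, were left out. The suffix _g_at, borne by the probe sets named for Igf2 and Mkrn1, was not excluded. From each list the up to 4 members past the threshold with the largest absolute difference were named, and 15 further genes were named whatever their values. Genes were also chosen after their values were seen where the text says so.

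The alternatives were a pseudocount of 1 or of the median signal, quantile normalization, median centring, no filter or a filter at the 75th percentile, moderation without a trend, an unmoderated test per probe set, scan day as a block or as a random block, only the preparations shared with chip A, and leaving out each array or preparation. For lists they included the mean of all probe sets of a gene and chip B before A. Chip lot divided chip A as scan day did and was single on chip B, and all chip C arrays shared 1 day, so no block could be fitted there. Analyses without the preparations ES 1 and TS 1, within a scan day, and of single TS arrays on chip C were chosen after seeing the data.

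The scripts were tested on simulated arrays, in 5 simulations with 200 changed probe sets each. These had the real probe set means and normal noise with the variance that limma gave after moderation with the trend. The simulations thus assume the trend and the moderation, and do not test whether they suit the real arrays. Of the probe sets changed by a log2 difference of 2, 70.7 percent were recovered on chip A, among 7090, 90.1 percent on chip B, among 6624, and 53.1 percent on chip C, among 8059. For a difference of 1 these shares were 15.5, 23.9 and 5.67 percent. False calls made up 6.08, 4.69 and 7.12 percent of the calls. With scan day as a block, 28.7 percent of the changes of 2 were recovered on chip A, with 11.7 percent false calls. In the simulation of lists on 9204 genes, each of the 17 lists shifted by 1 was found by camera at the preset correlation, and 11 of 17 were found with an estimated correlation. The simulated genes were independent, so this does not test whether the preset correlation suits the real lists. There the estimates ran from -0.086 (factors used by both cell types) to 0.454 (fibroblast markers), with 0.276 for keratins and junctions.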

Results

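The series set the RNA of 2 kinds of mouse stem cell side by side. R1 ES cells derive from the blastocyst, and were grown on gelatin with 15 percent serum and LIF, the cytokine that keeps mouse ES cells undifferentiated. The TS cells derive from the extraembryonic ectoderm, and were grown in RPMI medium with 20 percent serum and 25 ng/ml of FGF4. The labels put purity by visual inspection at 95 to 99 percent for the ES and 90 to 95 percent for the TS preparations, and state that differentiated cells of each kind may be present. The question the design poses is which genes differ between the cell types. Values are the deposited signals or log2 differences, TS minus ES, with the standard error (SE) from limma.

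On average, arrays of a cell type resembled each other more than arrays of different types. Across the tested probe sets, which are not independent replicates, the mean Pearson r on chip A was 0.857 within ES (1 pair), 0.871 within TS and 0.744 between the types. On chip B it was 0.762 within ES, 0.759 within TS and 0.622 between, and on chip C 0.860 within TS (1 pair) and 0.645 between. No 2 arrays held the same values. The arrays of the preparations ES 1 and TS 1 stood apart in antisense control signal and, on chip B, in correlation. On chip B, ES 1 correlated with the other ES arrays at 0.715 and 0.718, against 0.855 between those, and TS 1 with the other TS arrays at 0.681 and 0.735, against 0.861. ES 2 and TS 2, of different types, correlated at 0.684, above the lowest TS pair. On chip A the gap was smaller: TS 1 correlated with TS 2 and TS 3 at 0.879 and 0.849, against 0.885 between those. The 1 ES pair there cannot show which array stands apart. Antisense control probe sets read 3.35 to 3.63 percent of the sense controls in ES 1 and 5.11 to 5.45 percent in TS 1, against 0.902 to 2.49 percent on the other arrays.

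**Figure D1:**
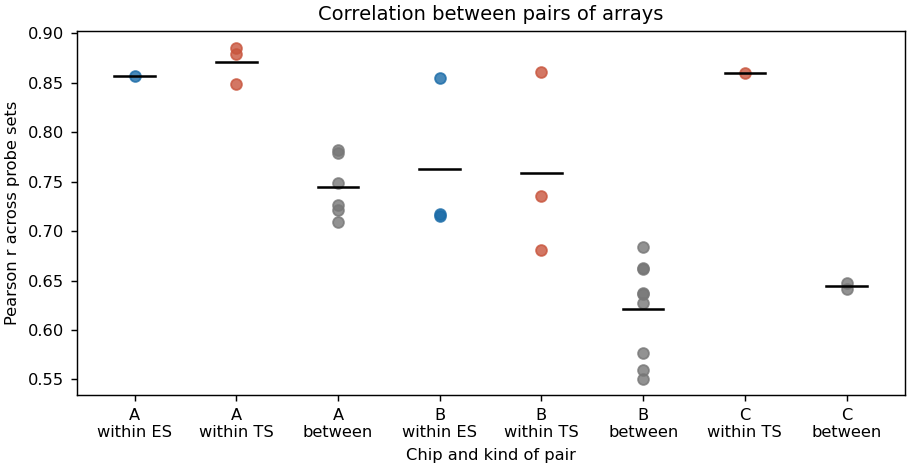
Pearson r across tested probe sets for each pair of arrays, by chip and by kind of pair (within ES, within TS or between the types); points are pairs and black bars are means. The means within a cell type, such as 0.871 for TS on chip A, lie above the mean between types of the same chip, 0.744 on chip A.

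On chip A, the genes with the largest differences included trophoblast and keratin genes among those higher in TS cells and pluripotency genes among those lower. Tinagl1, a secreted matrix protein, had a mean signal of 29221 ± 5413 (SD, n = 3) in TS and 301.5 ± 147 (SD, n = 2) in ES cells, a log2 difference of 5.83 ± 0.30 (SE, adjusted p = 1.9e-07). The growth factor Igf2 was 32.0-fold higher in TS cells with the pseudocount added (SE of the log2 difference 0.30) and the actin-bundling protein Lcp1 differed by 4.61 ± 0.32. Elf5, a transcription factor of the trophoblast lineage, differed by 4.55 ± 0.35, and Id2, an inhibitor of helix-loop-helix factors, by 4.32 ± 0.36. The simple epithelial keratins Krt7 and Krt18 differed by 4.23 ± 0.43 and 3.99 ± 0.27, and Isg15, a ubiquitin-like protein induced by interferon, by 3.96 ± 0.61. In the other direction, Dppa5a, an RNA-binding protein of pluripotent cells, fell from 86892 ± 33540 (SD, n = 2) in ES to 316 ± 291 (SD, n = 3) in TS cells, a log2 difference of -7.43 ± 0.42. The pluripotency factors Pou5f1 and Nanog differed by -5.35 ± 0.31 and -5.15 ± 0.43. Gsta4, a glutathione transferase, differed by -4.24 ± 0.47, and Meg3, a maternally expressed non-coding RNA, by -4.08 ± 0.41. Apoe (-3.52 ± 0.27), the F-box protein Fbxo15 (-3.37 ± 0.44) and the ubiquitin ligase Mkrn1 (-3.34 ± 0.31) completed the 8 lowest. All 16 of these passed the threshold, with adjusted p from limma between 1.9e-07 and 0.0010.

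In all, 598 of 7090 probe sets on chip A passed the threshold, 341 higher and 257 lower in TS cells, of which 148 and 78 differed by at least 4-fold. The groups did not overlap in 37.4 percent of the probe sets, where chance gives 20 percent. With scan day as a block, 467 passed. On chip A only day 1 held both cell types, with 1 array each (ES 1 and TS 1), so no test of that day alone was possible. The block fit takes its difference from these arrays alone and its spread from TS 2 and TS 3. Its count therefore does not show how the calls hold over replicates within a day. The count fell to 384 without ES replicate 1, to 386 without TS replicate 2, to 389 without the variance trend and to 0 in the unmoderated test, in which 1214 probe sets had an unadjusted p below 0.05. The balance moved too, to 341 higher and 132 lower without ES replicate 2 and 283 higher and 284 lower without TS replicate 3. With an ES array left out, the single ES array was assumed to vary like the TS arrays.

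**Figure D2:**
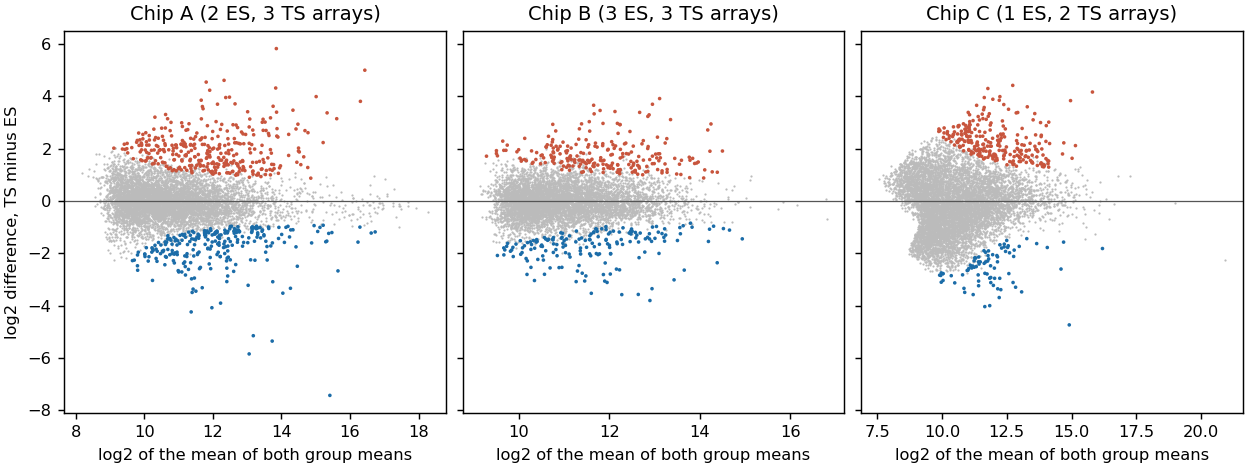
log2 difference (TS minus ES) against log2 of the mean of the group means, for the tested probe sets of chips A, B and C. Coloured points passed the threshold (red higher, blue lower in TS); on chip A these were 341 higher and 257 lower.

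Of the 15 genes fixed in advance, the ES-associated factors Zfp42 (-2.29 ± 0.32, adjusted p = 4.9e-04) and Fgf4 (-2.43 ± 0.35, adjusted p = 5.4e-04) were lower in TS cells, beside Pou5f1 and Nanog. Sox2, a factor of both cell types, was lower by a log2 difference of -1.75 ± 0.30 (adjusted p = 0.0022), from a probe set that can bind other transcripts. The TS cell factor Eomes (2.85 ± 0.34), the FGF receptor gene Fgfr2 (1.79 ± 0.28), Tfap2c (0.93 ± 0.25), Krt8 (2.61 ± 0.30), Hand1 (3.62 ± 0.41) and the X inactivation RNA Xist (3.20 ± 0.51) were higher, beside Elf5 and Krt18, with adjusted p from limma between 1.0e-06 and 0.035. Cdx2 and Esrrb did not pass. Cdx2, a trophectoderm factor, had a log2 difference of 0.34 ± 0.69 (limma adjusted p = 0.85). Its mean signal was 752 ± 946 (SD, n = 2) in ES and 724 ± 391 (SD, n = 3) in TS cells. The signal was 1421 in ES 1 and 83.1 in ES 2. In TS 1 and TS 3 it was 581 and 424, below the medians of these arrays, 759 and 612. So dim a probe set cannot show that Cdx2 is alike in the cell types. The difference was -0.87 without ES replicate 2, above 0.34 without ES replicate 1, and -1.03 with scan day as a block. Esrrb had -1.13 ± 0.44 (adjusted p = 0.15) on chip A and 0.09 ± 0.37 (adjusted p = 0.90) on chip C. Probe sets of a gene disagreed in size in places: other Pou5f1 probe sets gave -0.29 ± 0.59 on chip A and -0.47 ± 0.79 on chip C, a second Nanog probe set -1.73 ± 0.58, Meg3 -0.55 ± 0.50 on chip B, a second Lcp1 probe set 1.53 ± 0.55 and Apoe -0.77 ± 0.51 on chip C. In the other direction, Meg3 gave 0.28 ± 0.48, Mkrn1 0.10 ± 0.81, Sall4 0.01 ± 0.44, Grb10 -0.68 ± 0.37 and Mmp9 -0.94 ± 0.78 on chip C, and H2-K1 -0.25 ± 0.42 on chip A. None of these passed the threshold. A second Igf2 probe set on chip A was below the filter and went the other way, with mean signals of 592 in ES and 186 in TS cells. Of 119 genes with at least 2 probe sets past the threshold, 2 had opposite signs, Grina and Ip6k2, which were picked out after their values were seen.

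**Figure D3:**
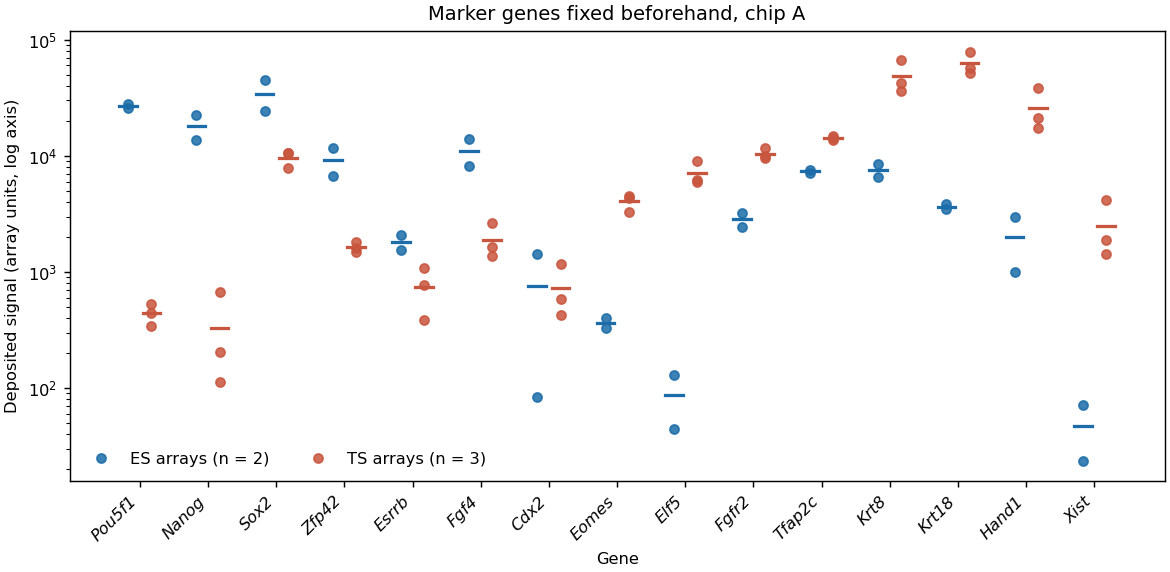
Deposited signals (log axis) of the genes fixed in advance that were measured on chip A, 1 point per array, with the mean as a bar, for 2 ES arrays (blue) and 3 TS arrays (red). Pou5f1 lies near 26698 in ES and 441 in TS cells, whereas the Cdx2 points of the groups, from a dim probe set, overlap.

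Chip B gave 407 of 6624 probe sets past the threshold, 234 higher and 173 lower in TS cells. The heparan sulfate sulfotransferase Hs3st3b1 was higher by a log2 difference of 3.92 ± 0.45, the ubiquitin ligase Rnf128 by 3.70 ± 0.36, the phosphatase subunit Ppp2r2c by 3.66 ± 0.35 and Cd55, an inhibitor of complement, by 3.46 ± 0.53. Oasl2, of the interferon-induced 2'-5' oligoadenylate synthetase family, differed by 3.42 ± 0.47 and Klhl22 by 3.39 ± 0.39. Ooep, an oocyte-expressed protein, had a signal of 11851 ± 2305 (SD, n = 3) in ES and 906 ± 944 (SD, n = 3) in TS cells, a log2 difference of -3.57 ± 0.44. Pycard, the adaptor of inflammasomes, differed by -3.53 ± 0.34, 1700019D03Rik by -3.08 ± 0.36, the cytoskeletal protein Add3 by -3.06 ± 0.31, the actin nucleator Cobl by -3.06 ± 0.38 and the deubiquitinase Usp28 by -3.01 ± 0.27. All 12 had adjusted p from limma between 1.7e-04 and 0.0026. A further Ppp2r2c probe set on chip B was also higher (2.36 ± 0.42, limma adjusted p = 0.0061), but another did not pass (-0.78 ± 0.53, in the other direction). Other probe sets on chip B did not pass for Add3 (-0.31 ± 0.44 and -1.40 ± 0.42) and Cobl (-1.14 ± 0.50). The groups did not overlap in 25.3 percent of the probe sets, where chance gives 10 percent. With scan day as a block, 383 passed, with 208 higher and 175 lower. Within day 1 (1 ES, 2 TS) 717 were higher and 298 lower, and within day 2 (2 ES, 1 TS) 65 were higher and 202 lower. Each day left 1 residual degree of freedom, and its single array of a cell type was assumed to vary like the pair of the other, so these counts are not comparable with the 407. The count was 780 without the preparations ES 1 and TS 1, a choice made after seeing the data, and 200, 206, 153 and 227 without ES replicate 2, ES replicate 3, TS replicate 2 and TS replicate 3; it was 17 in the unmoderated test. Without TS replicate 3, 101 were higher and 126 lower.

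Chip C, with a single ES array, gave 337 of 8059 probe sets past the threshold, 256 higher and 81 lower in TS cells. That array was assumed to vary like the 2 TS arrays, and none could be left out. These are differences from 1 ES array, and the spread between ES preparations was not measured. That array was of ES 1, whose arrays stood apart. Its antisense controls read 3.63 percent of the sense controls, against 1.15 percent in TS 2 and 0.966 percent in TS 3. Differences of cell type cannot be told apart here from those of this preparation. Tfpi, an inhibitor of the coagulation pathway, was higher by a log2 difference of 4.30 ± 0.47 (adjusted p = 1.9e-04), but its probe sets did not pass on chip A (1.02 ± 0.36, adjusted p = 0.11) or chip B (0.63 ± 0.46, adjusted p = 0.52). Next were the homeobox gene Rhox9 (4.17 ± 0.69, with 2.85 in TS 2 and 5.48 in TS 3) and Slc44a3, of the choline transporter-like family (3.99 ± 0.42). Dusp27 (-3.34 ± 0.72), the methylcytosine dioxygenase Tet1 (-3.23 ± 0.68) and the corepressor Nab1 (-3.13 ± 0.73) were lowest, with adjusted p up to 0.026. On chip A a Tet1 probe set gave -0.50 ± 0.62 and a Nab1 probe set, in the other direction, 0.60 ± 0.40 (adjusted p = 0.43); neither passed. The groups did not overlap in 79.3 percent of the probe sets, where chance gives 66.7 percent. The count was 157 with quantile normalization, 214 with the median as pseudocount, 132 with no filter and, in limma without the variance trend, 0, with 1849 at an unadjusted p below 0.05; after median centring, which moved the median of all probe sets from -0.09 to 0.19, 257 were higher and 24 lower.

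Chips A and B measured 950 genes in common, on the same preparations except ES 3, which was on chip B only. Their log2 differences correlated across genes with Pearson r = 0.462 and Spearman rho = 0.396. Of these genes 28 passed on both chips, all in the same direction. As the chips share preparations, differences between preparations would also give such agreement.

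Among the lists fixed in advance, pluripotency and ES cell markers fell. Of 36 members measured, 20 fell and none rose, and 27 fell when adjusted over the list alone. Dppa5a, Pou5f1, Nanog and Fbxo15 differed most. Among the 20, Sall1 (-2.92) and Eras (-1.44) were compared with the single ES array of chip C. The median log2 difference over the list was -1.74 (camera adjusted p = 5.3e-22, and adjusted p = 0.025 with an estimated correlation, the only list that passed so). Median differences were -2.16 over the list's genes on chip A and -2.07 there with scan day as a block, and on chip B they were -0.80 within day 1 and -1.41 within day 2. TS cell and extraembryonic ectoderm markers rose in 15 of 29 members and fell in none, with 18 adjusted over the list alone. Among the 15, Sox21 (3.39) was likewise compared with the single ES array of chip C. Elf5, Id2, Rhox9, from the single ES array of chip C, and Plet1, a surface protein of the early trophoblast (3.71 ± 0.36), rose most; the median was 1.61 (camera adjusted p = 2.5e-14, adjusted p = 0.059 with an estimated correlation), and on chip B 1.58 within day 1 and 1.15 within day 2. Keratins and epithelial junctions rose in 19 of 33 members and fell in 1, with 24 and 2 adjusted over the list alone. The member that fell was the gap junction gene Gja1 (-3.90 ± 0.35), from a probe set that can bind other transcripts. Krt7, Krt18 and the tight junction gene Cldn4 (3.12 ± 0.28) rose most. The median was 1.71 (camera adjusted p = 2.9e-16, adjusted p = 0.18 with an estimated correlation). On chip B, with 8 members, the list did not pass: the median was 0.28 (adjusted p = 0.13), 0.39 within day 1 (adjusted p = 0.17) and 0.60 within day 2 (adjusted p = 0.25).

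**Figure D4:**
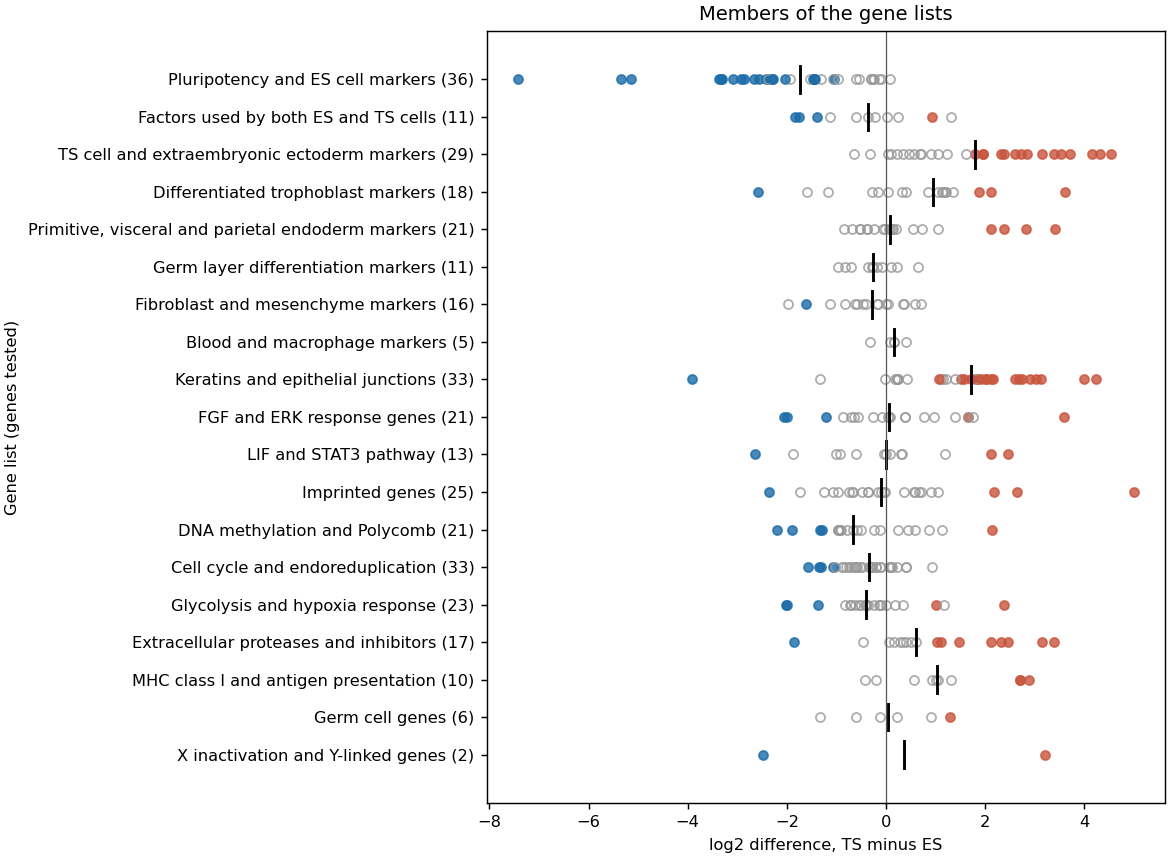
log2 difference (TS minus ES) of the measured members of each list. Filled points passed the threshold in the fit of their chip, open points did not, and black bars are the medians over all members shown; 20 of 36 pluripotency members lie filled below 0.

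Extracellular proteases and inhibitors rose in 8 of 17 members and fell in 1, as they did when adjusted over the list alone. On chips A and B, with 16 members, 4 rose without ES replicate 2 and without TS replicate 3, and 3 with scan day as a block. Serpinb9b (3.38 ± 0.70, from the single ES array of chip C, with 2.09 in TS 2 and 4.68 in TS 3), the matrix metalloproteinase Mmp9 (3.14 ± 0.48), the urokinase receptor Plaur (2.47 ± 0.42) and Serpinb9e (2.32 ± 0.50) rose most, at a median of 0.55 (camera adjusted p = 7.8e-04, adjusted p = 0.25 with an estimated correlation). MHC class I and antigen presentation genes rose in 3 of 10 members, B2m (2.88 ± 0.40), H2-D1 (2.70 ± 0.43) and H2-K1 (2.70 ± 0.37), with 5 adjusted over the list alone; the H2 probe sets can bind related genes. The median was 1.03 (camera adjusted p = 4.4e-04, adjusted p = 0.25 with an estimated correlation and 0.063 with fry), and 0.38 on chip A with scan day as a block. The signal of B2m was highest in TS 3 (11184, against 4880 in TS 1 and 4000 in TS 2). Cell cycle genes fell in 4 of 33 members, and in 4 adjusted over the list alone: the replication factors Pcna (-1.58 ± 0.29), Mcm3 (-1.36 ± 0.27), Mcm4 (-1.31 ± 0.29) and Mcm7 (-1.06 ± 0.27), at a median of -0.35 (camera adjusted p = 8.3e-04, adjusted p = 0.15 with an estimated correlation). The Mcm3 probe set can bind other transcripts. Of 31 members on chips A and B, 2 fell without ES replicate 1, without ES replicate 2 and with scan day as a block. DNA methylation and Polycomb genes fell in 4 of 21 members and rose in 1, with 8 and 1 adjusted over the list alone. Only 1 fell without ES replicate 2 and 2 with scan day as a block. The methyltransferase Dnmt3a (-2.20 ± 0.51), Hells (-1.89 ± 0.37) and Tet2 (-1.33 ± 0.31) fell and the Polycomb gene Cbx2 rose (2.13 ± 0.41), at a median of -0.67 (camera adjusted p = 0.0078, adjusted p = 0.18 with an estimated correlation).

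Glycolysis and hypoxia response genes fell in 3 of 23 members, Egln3 (-2.01 ± 0.32), Pdk1 (-1.999 ± 0.32) and Pgam1 (-1.37 ± 0.27), and rose in 2, among them Ndrg1 (2.38 ± 0.29), with the same counts adjusted over the list alone; the median was -0.41 (camera adjusted p = 0.022, adjusted p = 0.21 with an estimated correlation, 0.089 without ES replicate 2 and 0.067 without the preparations ES 1 and TS 1). Endoderm markers rose in 4 of 21 members, with 5 adjusted over the list alone, and none fell. They were the basement membrane genes Col4a1 (3.41 ± 0.28) and Col4a2 (2.38 ± 0.30), Sparc (2.83 ± 0.37) and Pth1r (2.13 ± 0.51), whereas the laminin genes Lama1, Lamb1 and Lamc1 had -0.84 ± 0.49, 0.06 ± 0.31 and 0.15 ± 0.41. The list's median was 0.10 and its mean 0.52 (camera adjusted p = 0.040, adjusted p = 0.36 with an estimated correlation, 0.18 without ES replicate 2 and 0.14 without TS replicate 1). With scan day as a block on chip A, camera gave adjusted p = 0.079 for the protease list, 0.054 for cell cycle, 0.25 for DNA methylation and 0.35 for glycolysis, which had 0.076 on chip A without the block. Their medians kept their direction, going from 0.60 to 0.97 for proteases, -0.34 to -0.45 for cell cycle, -0.63 to -0.45 for DNA methylation and -0.41 to -0.36 for glycolysis. In the same fit the endoderm list passed (camera adjusted p = 0.015), as did MHC class I (camera adjusted p = 0.014). The endoderm median went from 0.15 to 0.72 and that of MHC class I from 1.03 to 0.38. That fit rests on the difference between ES 1 and TS 1.

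The other lists did not shift past the threshold over chips A and B together. None of them passed with an estimated correlation either, where differentiated trophoblast markers had camera adjusted p = 0.25. Chip B alone was tested at the preset correlation only. Factors used by both cell types fell in 3 of 11 members, Mycn (-1.84 ± 0.33), Sox2 and Sall4 (-1.38 ± 0.33), and rose in 1, Tfap2c, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.097). Differentiated trophoblast markers rose in 3 of 18, Hand1, Nrk (2.12 ± 0.52) and Flt1 (1.88 ± 0.49), and fell in 1, Plac8 (-2.59 ± 0.34), with 4 and 1 adjusted over the list alone (adjusted p = 0.092, and 0.023 without ES replicate 1). The 3 members on chip B alone passed as a list, at a median of 1.502 (adjusted p = 0.032, 0.031 with scan day as a block and 0.033 within day 1), but not within day 2 (adjusted p = 0.13). Fibroblast markers fell in 1 of 16, Tagln (-1.62 ± 0.39), as they did over the list alone (adjusted p = 0.11, and 0.024 and 0.045, in the direction of lower in TS, without TS replicate 1 and TS replicate 2). Imprinted genes rose in 3 of 25, Igf2, Cdkn1c (2.64 ± 0.48) and Grb10 (2.17 ± 0.34), and fell in 1, Meg3, with 5 and 2 adjusted over the list alone; the median was -0.04 and the mean 0.29 (adjusted p = 0.40). FGF and ERK response genes rose in 2 of 21, Fgfbp1 (3.60 ± 0.36, from the single ES array of chip C) and Dusp5 (1.65 ± 0.29), and fell in 3, among them Epha2 (-2.06 ± 0.41) and Etv5 (-2.003 ± 0.34), with 5 and 3 adjusted over the list alone (adjusted p = 0.95). LIF and STAT3 pathway genes rose in 2 of 13, Cebpb (2.46 ± 0.34) and Jak1 (2.13 ± 0.41), and fell in 1, Icam1 (-2.65 ± 0.64), with 3 and 4 adjusted over the list alone; the median was 0.01 and the mean -0.05 (adjusted p = 0.96). The probe sets of Fgfbp1 and Grb10 can bind other transcripts. None of 11 germ layer markers (adjusted p = 0.47) and none of 5 blood markers (adjusted p = 0.95) passed. Tex19.1 (1.29 ± 0.28) rose among 6 germ cell genes, also adjusted over the list alone. Of 2 measured X inactivation and Y-linked genes, Xist rose and Eif2s3y (-2.48 ± 0.69, adjusted p = 0.042) fell, also over the list alone; the Eif2s3y probe set can bind related genes. It did not pass without ES replicate 1, ES replicate 2, TS replicate 2 or TS replicate 3. The calls of Tfap2c, Mcm3, Mcm4, Mcm7, Pgam1, Sall4, Tagln, Hells, Dnmt3a, Tet2, Epha2, Flt1, Nrk, Pth1r, Serpinb9e and Icam1 also ended with at least 1 array left out, and those of Mycn and Tex19.1 with scan day as a block.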

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

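The calls of each chip and the lists were recomputed under each of the other settings fixed beforehand; analyses without the preparations ES 1 and TS 1 and within a scan day were chosen after seeing the data. No paired analysis was possible because the ES labels carry no replicate numbers that the TS preparations share. No probe set that passed in the main setting changed direction in any alternative that tested it. None of the named genes past the threshold did either. This was partly fixed by how the probe sets were selected. Where the groups do not overlap, as was required of genes named by rank, some settings cannot reverse the direction. These are leaving out arrays, scan day as a block and another pseudocount. Of the 89 named probe sets past the threshold, 83 to 88 still passed with other pseudocounts, scalings or no filter, 75 without the variance trend, 3 of 81 on chips A and B in the unmoderated test, and 69 of 81 with scan day as a block; leaving out an array of those present on both chips ended 4 to 13 of 81 calls. On chip A the count of calls was 389 without the variance trend, 0 in the unmoderated test and 384 to 567 when an array was left out. On chip B it was 17 in the unmoderated test, 206 with only the preparations also on chip A, 1015 and 267 within scan days 1 and 2, 780 without ES 1 and TS 1, and 153 to 547 when an array was left out. On chip C it was 214 with the median as pseudocount, 157 with quantile normalization, 132 with no filter and 0 without the variance trend; with 1 ES and 2 TS arrays, leaving any array out allowed no test, and single TS arrays were compared with the ES array only as values, a choice made after seeing the data. Leaving out arrays also leaves fewer of them, but on chip B the count rose to 547 without TS replicate 1. The cause of these changes was not tested. The lack of detection calls and the high floor of dim signals limit what can be said of dim genes.

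With an estimated correlation the adjusted p was 0.059 for TS cell markers, 0.18 for keratins and junctions, 0.18 for DNA methylation and Polycomb, 0.15 for cell cycle, 0.21 for glycolysis, 0.25 for proteases, 0.25 for MHC class I and 0.36 for endoderm, all past the threshold in the main setting. With fry it was 0.016 for factors of both cell types, 0.037 for imprinted genes, 0.063 for MHC class I and 0.13 for endoderm. The endoderm list gave 0.056 after median centring and 0.34 with no filter, and differentiated trophoblast 0.039 with chip B before A and 0.013 without ES 1 and TS 1, which left glycolysis at 0.067. Leaving out a preparation gave adjusted p of 0.023 to 0.18 for differentiated trophoblast, 0.0072 to 0.18 for endoderm, 0.024 to 0.77 for fibroblast markers and 0.011 to 0.089 for glycolysis. The correlation of chips A and B was 0.328 with no filter and 0.626 with the filter at the 75th percentile. The mean correlation within minus that between cell types was 0.0613 and 0.218 on chip A, 0.0572 and 0.264 on chip B, and 0.137 and 0.291 on chip C under these filters, and on chip C 0.257 with a pseudocount of 1, 0.187 with the median and 0.202 with quantile normalization. Cdx2 turned to -1.03 with scan day as a block and ranged from -0.87 to 1.56 when an array was left out, and Tet1 on chip A from -1.02 to 0.025; neither had passed, and the cause was not tested.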

Other observations

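The gene families and all tests in this part were chosen after the values were seen, except the count of splits of chip B. Among 13 further families, interferon-stimulated genes were higher in TS cells: of 26 measured on chips A and B, 7 passed the threshold higher, including Isg15, Oasl2, Ifi35 (2.99 ± 0.56), Rsad2 (2.59 ± 0.71), Usp18 (2.49 ± 0.66), Lgals3bp (1.95 ± 0.44) and Bst2 (1.91 ± 0.37), and 1 lower, Ifitm3 (-3.22 ± 0.79). With each array left out in turn, Isg15, Oasl2, Ifi35 and Bst2 passed throughout. Without TS 3, Rsad2 (1.48, limma adjusted p = 0.13), Usp18 (1.70, adjusted p = 0.16) and Lgals3bp (1.84, adjusted p = 0.072) did not. The losses were not confined to TS 3. Rsad2 also did not pass without ES 1, ES 2 or ES 3, Usp18 without ES 2, and Lgals3bp without ES 2 or TS 2. Ifitm3 did not pass without ES 1, ES 2 or TS 2. The family's median log2 difference was 0.61 (camera adjusted p = 0.0018 over the 13, adjusted p = 0.63 with an estimated correlation); Isg15 and Oasl2 had already been seen among the highest, so this is not independent. Genes of actin regulation had 6 of 22 higher, among them Gsn (2.66 ± 0.35), Tagln2 (2.23 ± 0.25) and Capg (1.69 ± 0.31) beside Lcp1, at a median of 0.43 (adjusted p = 0.0034). Cholesterol synthesis genes had a median of -0.71 over 15 genes (adjusted p = 0.0034), but only Idi1 (-2.54 ± 0.40) passed alone. These 2 families had adjusted p = 0.57 with an estimated correlation. Spliceosome proteins (-0.43, adjusted p = 0.037), the chaperonin complex (-0.41, adjusted p = 0.046) and ribosomal proteins (-0.16, adjusted p = 0.046) passed with the deposited scaling, at adjusted p = 0.63 with an estimated correlation; the ribosomal median was 0.01 after quantile normalization and the chaperonin adjusted p was 0.052 after median centring. With a preparation left out their adjusted p reached 0.21, 0.16 and 0.43, so none of these 3 held throughout. Respiratory chain, proteasome, tRNA synthetase, glutathione transferase, histone, zinc finger and solute carrier genes did not pass, with adjusted p of 0.24, 0.20, 0.86, 0.45, 0.99, 0.12 and 0.44.

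Over the 36 interferon-stimulated and MHC class I genes together the median difference was 0.97 ± 0.29 (standard error of the median over genes, as in the tests that follow, which takes genes as independent). Of the 36, 30 had a higher signal in TS 3 than in TS 1 and TS 2, with a median of TS 3 minus the mean of TS 1 and TS 2 of 1.18 ± 0.20, against 0.03 over all genes. Other groups were also higher in TS 3, though less: keratins and junctions by 0.56 ± 0.14, proteasome subunits by 0.56 ± 0.10, proteases by 0.50 ± 0.17, the chaperonin complex by 0.49 ± 0.20, spliceosome proteins by 0.42 ± 0.17 and respiratory chain subunits by 0.22 ± 0.10, so the excess was not particular to interferon and MHC genes. Without TS 3 the median difference was still 0.59 ± 0.29, above 0 by barely more than 2 standard errors. These take genes as independent, whereas the MHC class I list had an estimated correlation of 0.283, so TS 3 alone as the source is not excluded. After quantile normalization the excess in TS 3 was 1.19 ± 0.18, which argues against the wider signal range of its arrays. RNA of fibroblasts would raise the 14 fibroblast markers, whose median was -0.29 ± 0.25 between TS and ES and -0.996 ± 0.20 between TS 3 and the other TS preparations; Col1a1 gave 3234, 671 and 190.5 in TS 1, TS 2 and TS 3 against 1877 and 2463 in ES 1 and ES 2, so TS 1 went the other way, and Fn1 gave 9897, 6150 and 4313 against 15177 and 8798. TS 2 and TS 3 were scanned on the same day on every chip; a larger share of differentiated trophoblast in TS 3 stays open (median of 11 markers -0.24 ± 0.26), as do the cell type itself and the medium and serum, which differed with it, so an interferon-like state that varies between TS preparations is a candidate explanation only.

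The arrays of ES 1 and TS 1 stood apart in antisense control signal and, on chip B, in correlation. On days shared with other preparations their antisense signal was at least 2.18 times that of the highest other array of the day. Those others differed by at most 1.597 times. On day 2 of chip A, which held neither preparation, TS 2 and TS 3 read 2.40 and 0.902 percent, a factor above 2.18. Arrays of a day can thus differ as much without ES 1 or TS 1. On chip B, ES 1 read 3.35 percent on day 1, beside 1.30 in TS 2 and 1.16 in TS 3. TS 1 read 5.45 percent on day 2, beside 2.49 in ES 2 and 1.56 in ES 3. On chip C, of 1 day, ES 1 read 3.63 percent, against 1.15 and 0.966. These values argue against scan day as the source of the antisense signal on chips B and C. Day 1 of chip A held only ES 1 and TS 1, so the day was not settled there. In correlation on chip B the day stays open. There ES 1 and TS 1 were each scanned on another day than the rest of their type. Shortened RNA could not be settled: the actin 3' to 5' ratio was 1.402 to 1.56 in ES 1, but 1.29 to 1.31 in TS 1, whose lowest value was 1.01 times the highest of the other arrays (1.05 to 1.28). Each cell type held 1 such preparation, and no biological explanation was tested.

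Xist was higher in TS cells, and the Y-linked Eif2s3y lower. Binding of the Eif2s3x transcript to the Eif2s3y probe set would make the X-linked gene fall alike, but Eif2s3x differed by -0.26 ± 0.25 against -2.48 ± 0.69. ES cells with and TS cells without a Y chromosome remain a possible explanation that these arrays leave open, because the other Y-linked genes on chip A, Kdm5d and Uty, reached at most 313 on any array, near the chip's 25th percentile of 221.7. On chip B, below the filter, 2 Kdm5d probe sets, the second of which can bind related genes, had means of 362 and 247 in TS and 166 and 188 in ES cells, with up to 918 on a TS array; so near the floor these values exclude nothing.

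On chip B, limma passed 407 probe sets for the real split of the 6 arrays, and 0 in each of the other splits, of which the highest number at an unadjusted p below 0.05 was 453, against 1272 for the real one. The split that follows scan day gave 0 as well, with 447 in limma at an unadjusted p below 0.05. In each split other than the real one the difference between ES and TS adds to the spread within the sides, which lowers the count. The 0 for scan day therefore does not exclude an effect of the day. Counting the real split itself, 1 of the 10 splits reached 407, and 10 are too few for a share under 0.05.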
